A study of Caenorhabditis elegans with 12 samples.

How the data were processed

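Polyadenylated RNA of 12 samples of whole L4 animals was extracted with Trizol and made into unstranded NEBNext Ultra libraries for paired-end sequencing, with 4 libraries in each of the unexposed, naive and bookmarked groups. The deposited count table holds raw counts per gene for 42048 genes, as whole numbers, one column per library. The submitters' processing notes name STAR 2.5.0, featureCounts 1.6.2, edgeR 3.24.3 and the genome build ce10, without their settings. The authors also deposited a comparison table of 15925 genes with fold changes and average levels on a log2 scale. Per the file headers that table also gives a p-value and an adjusted p-value per gene and comparison, with neither the test nor its covariates stated. The fold changes were read as log2 because they were signed, additive over the 3 comparisons, and differed from those fitted here by a median of 0.000620 to 0.00142. The authors' table was used only for the comparison given in the closing part and for changes against unexposed animals of some genes lower in bookmarked than naive animals. Gene names were kept as deposited: 38832 matched a symbol of the reference annotation, and 11 had been altered to dates, which were left unnamed. The reference annotation is of another genome build (WBcel235) than the one in the notes, so no coordinates are given.

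Total counts ranged from 9252823 to 14640115 per library. Genes with too few counts for a test were left out with the edgeR function filterByExpr, which kept 14638 genes and left out 27410. Counts were scaled by the trimmed mean of M values (TMM), and all 12 libraries were fitted together with 1 mean per group in edgeR 4.0.16 under R 4.3.3 (robust quasi-likelihood fit and test). A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. The SE of a log2 fold change is its size divided by the square root of the test's F. The p-values weigh group differences against the spread between these libraries that the fit leaves unexplained. Levels are CPM with the SD over the 4 libraries of a group. A level of 1 CPM is about 10 reads in these libraries, so low levels carry the most counting error.

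The experiment numbers in the column headers of the deposited tables, 16, 28, 29 and 30, link replicates 1 to 4 across the groups. Correlations of log2 levels, centred within groups, were 0.665 to 0.886 between libraries of the same number and at most 0.679 between others, and every library was best correlated with one of its own number. The planned fit has no such term, and a fit with the replicate number as a block is given beside it. The common biological coefficient of variation was 0.452 without and 0.148 with the block. Without the block 341, 300 and 357 of 14638 genes had an unadjusted edgeR p below 0.05. These counts are for naive against unexposed, bookmarked against unexposed and bookmarked against naive animals. Each is below the share of 0.05 that chance alone gives, so the test without the block was conservative. No library was a copy of another of its group: in the 18 pairs within groups, differences between their counts exceeded counting error, with a chi-square per degree of freedom of 29.5 to 143. Counts were also simulated with the spread of all 12 libraries. In those for the fit without the block, libraries of an experiment shared no differences, unlike the real ones. That fit recovered 15.3% of genes changed by 1 on the log2 scale and 65.3% of those changed by 2, with 1 false call among 80. These shares may therefore not hold for the real libraries. With the block it recovered 70% and 96%, with 9 false calls among 175.

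Before the data were examined, the comparisons, the test, the alternatives, the rule for named genes and 31 gene lists were fixed. The lists were HIF-1 response genes, sulfide oxidation and sulfur amino acid metabolism, SKN-1 and phase II detoxification, cytosolic heat shock genes, the endoplasmic reticulum and mitochondrial unfolded protein responses, metal-responsive genes, antioxidant enzymes, DAF-16 targets, innate immune effectors, cytochrome P450 and UDP-glucuronosyltransferase genes, H3K4 methylation, SWI/SNF and ISWI remodelling, histones, cytosolic ribosomal proteins, the proteasome, the respiratory chain, mitochondrially encoded genes, glycolysis, fatty acid desaturation and oxidation, autophagy, collagens, molting, sperm, vitellogenin and oocyte, germline, neuronal, muscle, intestinal and pharyngeal genes. No mitochondrially encoded gene was in the count table under the names searched, so 30 lists with at least 5 tested members were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01), adjusted over the lists of a comparison, and again with the correlation estimated per list. Some genes are in more than 1 list: cysl-2 (HIF-1 and sulfur), gcs-1 (sulfur and SKN-1), ugt-11 (SKN-1 and UDP-glucuronosyltransferase), hsp-12.3, hsp-12.6 and sip-1 (heat shock and DAF-16), sod-3 and ctl-2 (antioxidant and DAF-16), mtl-1 (metal and DAF-16), mtl-2 (metal and intestine) and gpd-2 (mitochondrial response and glycolysis).

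Genes were named by a rule with 3 parts. They were the 8 with the largest change each way among called genes with an average log2 CPM of at least 2 and groups that did not overlap; the 3 members of smallest p of each list called by camera; and 14 fixed genes, which were sqrd-1, ethe-1, cysl-1, cysl-2, rhy-1, egl-9, nhr-57, hif-1, skn-1, gst-4, gcs-1, hsp-16.2, mtl-1 and set-2. After the data were seen, the first part was repeated on the fit with the block, and 10 genes were added: hsp-110, hsp-43, dnj-13, pek-1, unc-23, cysl-3, Y37A1B.5, C31C9.2, F26H9.5 and Y62E10A.13. Unstranded reads cannot be told apart where genes overlap. This applies to rhy-1 (with W07A12.8), nhr-57 (lgc-1), cysl-2 (vnut-1), cysl-3 (rips-1), cdo-1 (F56F10.2), mpst-3 (H12D21.6), nit-1 (ZK1058.9), hsp-70 (uggt-2), gst-4 (dhs-12), nhr-17 (nlp-76), lact-4 (M05D6.3), cyp-36A1 (figo-1), R08E5.1 (R08E5.4), F26H9.5 (uev-3), unc-23 (T19A5.3), rpl-39 (grl-10), F45E1.4 (sdpn-1), dnj-13 (dhgd-1), fbf-1 (H12I13.6), aagr-1 (D2096.6), skn-1 (csn-5 and clec-178) and sqrd-1 (several piRNAs). Non-coding genes also overlap egl-9 (Y32F6B.6, Y32F6B.8 and the piRNA 21ur-15622), bec-1 (T19E7.24), nhr-3 (H01A20.4), T28F4.1 (T28F4.7) and ethe-1 (the piRNA 21ur-14079). C31C9.2, R08E5.3 and Y37A1B.5 were not found under these names in the annotation, so their overlaps were not looked up. Close copies, such as R08E5.1 and R08E5.3, the nspe genes and the hsp-16 genes, share sequence, and the notes do not state how reads with several matches were counted.

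The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, no filter on counts, at least 1 CPM in at least 4 libraries, a fit of only the 8 libraries compared, the replicate block, stricter thresholds and leaving out each library in turn. For lists they were camera with an estimated correlation and fry. Alternatives to the fit with the block, leaving out a replicate number in every group, and the block with an estimated correlation were added after the data were seen. Calls shared by the exposed groups were compared with the count for independent lists, with 20 simulations of unchanged groups and with the unexposed libraries divided between the comparisons. The relative response size is the slope through the origin of the bookmarked on the naive log2 changes, for genes called in 2 experiments and measured in the other 2. No per-library column was left unused.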

Results

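Polyadenylated RNA was sequenced from whole Caenorhabditis elegans at the fourth larval stage (L4), grown at 20 °C, in 3 groups of 4 libraries each. Unexposed animals stayed in house air. Naive animals were exposed to hydrogen sulfide (H2S) above 150 ppm for 1 h before collection. Bookmarked animals had been kept at 50 to 60 ppm H2S early in life and held in house air for about 24 h before the same acute exposure. The labels place the early exposure both in embryos for about 8 h and from the first larval stage for 8 to 12 h, and the data do not settle which was done. Libraries are named by group and replicate number as U1 to U4 (unexposed), N1 to N4 (naive) and B1 to B4 (bookmarked). Total counts were 13818462, 9557833, 9870127 and 9268745 in U1 to U4. They were 14640115, 9710858, 10033921 and 9252823 in N1 to N4, and 13563573, 11633184, 9556087 and 11263043 in B1 to B4. Levels are mean CPM (counts scaled to library size) ± SD and fold changes are on the log2 scale ± SE, with n = 4 per group. Replicates 1 to 4 came from experiments 16, 28, 29 and 30, and values fitted with the replicate number as a block stand beside those without it wherever they differ in a call.

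The comparison of naive with unexposed animals asked which transcripts an acute H2S exposure changed in animals with no earlier exposure. Genes of the hypoxia-inducible factor (HIF-1) pathway rose within the hour. rhy-1, a regulator that acts upstream of HIF-1, rose from 15.8 ± 2.11 to 343 ± 68.9 CPM, a log2 fold change of 4.44 ± 0.26 (edgeR adjusted p = 2.3e-05). nhr-57, a nuclear receptor gene widely used as a HIF-1 reporter, rose from 5.02 ± 1.02 to 90.3 ± 29.4 CPM, by 4.16 ± 0.28 (edgeR adjusted p = 4.6e-05). egl-9, which encodes the prolyl hydroxylase that marks HIF-1 for degradation, rose by 1.71 ± 0.19 to 68.9 ± 3.0 CPM (edgeR adjusted p = 0.0021). hif-1 itself was measured at 190 ± 30.9 CPM in unexposed and 222 ± 48.6 CPM in naive animals (edgeR adjusted p = 1.00).

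Of the 9 HIF-1 response genes tested, 6 rose, 0 fell (0 also at an unadjusted p below 0.05 and in the other tools) and 3 did not pass. The count was 8 adjusted over the list alone. Their median log2 fold change was 1.94 (camera adjusted p = 2.7e-50, and camera adjusted p = 9.5e-05 with an estimated correlation). Of 22 genes of sulfide oxidation and sulfur amino acid metabolism, 3 rose and 19 did not pass. Adjusted over the list alone 6 rose, and 6 rose with the block. The risers were sqrd-1, the sulfide quinone oxidoreductase of mitochondrial H2S oxidation, cysl-2, a cysteine synthase-like gene that also belongs to the HIF-1 list, and cdo-1, a cysteine dioxygenase. sqrd-1 went from 3.13 ± 0.985 to 45.3 ± 10.8 CPM, a rise of 3.86 ± 0.34 (edgeR adjusted p = 5.4e-04), cysl-2 rose by 2.00 ± 0.23 (edgeR adjusted p = 0.0032) and cdo-1 by 1.40 ± 0.17 (edgeR adjusted p = 0.0049). The sulfur list passed as a whole (camera adjusted p = 3.2e-10, and camera adjusted p = 0.032 with an estimated correlation). ethe-1, a sulfur dioxygenase, stood at 3.71 ± 0.828 CPM in unexposed and 6.996 ± 1.07 CPM in naive animals (0.91 ± 0.31, edgeR adjusted p = 1.00, and 0.049 with the block). With the block the call for ethe-1 was lost without any 1 of U1 to U4, N1 to N3 or B1 to B3 (edgeR adjusted p 0.055 to 0.21). cysl-1, an upstream H2S-responsive regulator of the pathway, did not pass (0.34 ± 0.17, edgeR adjusted p = 1.00).

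Among 20 SKN-1 and phase II detoxification genes, 3 rose and 17 did not pass. Both adjusted over the list alone and with the block 4 rose (camera adjusted p = 1.2e-14, and camera adjusted p = 0.020 with an estimated correlation). nit-1, a nitrilase, rose from 8.17 ± 2.09 to 54.2 ± 7.23 CPM, by 2.73 ± 0.28 (edgeR adjusted p = 0.0014). dhs-8, a short-chain dehydrogenase, rose by 3.20 ± 0.45 (edgeR adjusted p = 0.015), a call lost without U3, N3 or N4 (edgeR adjusted p 0.054 to 0.068). wdr-23, the negative regulator of the transcription factor SKN-1, rose by 0.67 ± 0.10 (edgeR adjusted p = 0.029), a call lost without any 1 of U1 to U4, N2 to N4, B2 or B4 (edgeR adjusted p 0.055 to 0.15). skn-1 was higher by 0.56 ± 0.16 (edgeR adjusted p = 0.66, and 0.0060 with the block). gcs-1, a SKN-1 target in glutathione synthesis, was measured at 69.3 ± 14.4 and 78.0 ± 20.9 CPM (edgeR adjusted p = 1.00). The level of gst-4, a glutathione S-transferase, was 18.7 ± 1.89 and 24.1 ± 8.64 CPM (edgeR adjusted p = 1.00). Outside the lists the largest fold change among the genes of the naming rule was that of gst-19, another glutathione S-transferase, which rose from 1.07 ± 0.247 to 34.9 ± 16.06 CPM, by 5.01 ± 0.44 (edgeR adjusted p = 5.4e-04). R11A5.3 rose by 4.04 ± 0.68 (edgeR adjusted p = 0.045), lost without any 1 of U2 to U4, N1 to N4 or B2 to B4 (edgeR adjusted p 0.059 to 0.22). The nspe genes nspe-4 and nspe-6, near-identical copies between which reads may not be separable, rose by 4.42 ± 0.72 and 4.91 ± 0.82 (edgeR adjusted p = 0.041 and 0.045). Both calls were lost without any 1 of U1 to U4, N2, N3 or B2 to B4, and that of nspe-6 also without B1 and with the block (edgeR adjusted p 0.066 to 0.21 without a library and 0.18 with the block).

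Some cytosolic heat shock genes passed in naive animals, in the edgeR quasi-likelihood test only with the block. hsp-70, an inducible cytosolic chaperone, was measured at 11.6 ± 13.4 CPM in unexposed and 194 ± 45.6 CPM in naive animals, a difference of 4.05 ± 0.91 (edgeR adjusted p = 0.24). It passed with the block (4.59 ± 0.60, edgeR adjusted p = 0.025). hsp-16.2, a small heat shock protein gene with close copies, stood at 8.25 ± 8.38 and 89.6 ± 17.9 CPM (3.43 ± 0.86, edgeR adjusted p = 0.37). It, too, passed with the block (3.92 ± 0.58, edgeR adjusted p = 0.036). With the block, hsp-70 was lost without any 1 of U1 to U3, N2, N3, B2 or B3 (edgeR adjusted p 0.057 to 0.12). The call of hsp-16.2 was lost without any 1 of U1 to U4, N2 to N4 or B2 to B4 (edgeR adjusted p 0.066 to 0.15). Of the 16 heat shock genes tested, 0 rose without the block in edgeR (8 at an unadjusted p below 0.05, 3 in DESeq2, 1 in limma-voom, 2 in the likelihood ratio test). The count was 5 adjusted over the list alone and 5 with the block. The list passed upward (median 0.40, camera adjusted p = 1.4e-11), but its adjusted p = 0.058 with an estimated correlation did not pass. Chosen after the values were seen, hsp-110, a co-chaperone of the same list, was higher by 0.95 ± 0.37 (edgeR adjusted p = 1.00, and 6.4e-04 with the block). Also chosen then, pek-1, the stress kinase of the endoplasmic reticulum, was higher by 1.17 ± 0.28 (edgeR adjusted p = 0.31, and 3.2e-05 with the block). The value of unc-23, a chaperone cofactor, was higher by 1.13 ± 0.29 (edgeR adjusted p = 0.38, and 2.4e-04 with the block). U1 was above U2 to U4 for several heat shock genes, with hsp-70 at 31.3 CPM against 1.53 to 7.17 CPM.

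Among 58 UDP-glucuronosyltransferase genes, 0 rose without the block (edgeR; 3 at an unadjusted p below 0.05, 2 in DESeq2, 0 in limma-voom, 1 in the likelihood ratio test). In this list 1 rose adjusted over the list alone and 3 rose with the block. That list passed (camera adjusted p = 1.2e-05), but not with an adjusted p = 0.11 with an estimated correlation. ugt-8 was higher by 1.85 ± 0.32 (edgeR adjusted p = 0.059, 4.5e-05 with the block and 0.037 without B1), and ugt-13 by 1.42 ± 0.37 (edgeR adjusted p = 0.44, and 0.0017 with the block). Among 22 autophagy genes, 0 rose without the block (edgeR; 2 at an unadjusted p below 0.05, 2 in DESeq2, 0 in limma-voom, 1 in the likelihood ratio test). In this list 2 rose adjusted over the list alone and 2 with the block (camera adjusted p = 1.8e-05, and camera adjusted p = 0.032 with an estimated correlation). These were sqst-1, the p62 cargo receptor (1.04 ± 0.21, edgeR adjusted p = 0.13, and 3.2e-05 with the block), and bec-1, the Beclin homolog (0.69 ± 0.16, edgeR adjusted p = 0.27, and 0.0045 with the block). The 15 DAF-16 target genes passed as a list (camera adjusted p = 2.4e-05, and camera adjusted p = 0.032 with an estimated correlation). So did 9 metal-responsive genes (camera adjusted p = 8.5e-04, and camera adjusted p = 0.041 with an estimated correlation). Of their members 0 rose without the block in edgeR (3 and 1 at an unadjusted p below 0.05, 0 in DESeq2, limma-voom and the likelihood ratio test). Adjusted over the list alone 1 and 0 rose, and 1 of each rose with the block. Neither the DAF-16 nor the metal list passed in fry (fry adjusted p = 0.066 and 0.072), nor did the autophagy list (fry adjusted p = 0.066). The metallothionein gene mtl-1 was near the detection limit at 1.01 ± 0.517 and 1.90 ± 0.643 CPM (edgeR adjusted p = 1.00). Of 51 cytochrome P450 genes 0 rose without the block (edgeR; 3 at an unadjusted p below 0.05, 1 in DESeq2, 0 in limma-voom, 1 in the likelihood ratio test). Of these, 1 rose adjusted over the list alone and 3 with the block (camera adjusted p = 0.0094). The P450 list was lost at an adjusted p = 0.46 with an estimated correlation, and without U1, N3 or N4 (camera adjusted p 0.086 to 0.22). cyp-36A1 was higher by 1.43 ± 0.25 (edgeR adjusted p = 0.059, 0.0045 with the block and 0.035 to 0.037 without B3 or B4).

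No gene was called lower without the block (edgeR, 0 genes; 72 were lower at an unadjusted p below 0.05, 3 in DESeq2, 2 in the likelihood ratio test and 0 in limma-voom), and 17 were called lower with it. Without the block 341 of 14638 genes had an unadjusted p below 0.05 in either direction, under the share of 0.05 that chance alone gives. The test was thus conservative, and its 0 calls do not show that no gene fell. ZK6.8 stood at 24.4 ± 8.57 CPM in unexposed and 7.64 ± 2.88 CPM in naive animals (-1.67 ± 0.40, edgeR adjusted p = 0.30, and 3.2e-05 with the block). swt-3, a SWEET-family sugar transporter gene, was measured at 102 ± 21.6 and 58.4 ± 9.31 CPM (-0.81 ± 0.17, edgeR adjusted p = 0.16, 0.0047 with the block and 0.040 without U1). rpl-39, of the 60S ribosome, differed by -0.74 ± 0.19 (edgeR adjusted p = 0.42, 0.024 with the block and 0.049 without N4). Its blocked call was lost without any 1 of U1 to U3 or N1 to N3 (edgeR adjusted p 0.076 to 0.15). As lists, 74 sperm genes (median -0.37, camera adjusted p = 2.6e-04) and 19 vitellogenin and oocyte genes (median -0.50, camera adjusted p = 2.4e-04) were lower in naive animals. Neither held with an estimated correlation (adjusted p = 0.94 and adjusted p = 0.80 with an estimated correlation). U1 had a mean log2 CPM of 3.29 over the sperm list and 7.54 over the oocyte list, against 1.67 and 5.60 in N1 of the same experiment. The sperm list was lost without U2, U3, N1 or N4 (camera adjusted p 0.076 to 0.97). The oocyte list was lost without U2 or N4 (camera adjusted p 0.14 to 0.68). The 27 histone genes (median -0.16, camera adjusted p = 0.013) were lost without U3 or N1 (camera adjusted p 0.11 to 0.18) and at an adjusted p = 0.47 with an estimated correlation. The 76 cytosolic ribosomal protein genes (median -0.02, camera adjusted p = 0.022) were lost without U1, U4, N2 or N3 (camera adjusted p 0.17 to 0.94), with the block (camera adjusted p = 0.089) and at an adjusted p = 0.94 with an estimated correlation. In these 4 lists 0 members fell without the block (edgeR, also adjusted over the list alone), and with it 1 sperm and 1 ribosomal gene fell. At an unadjusted p below 0.05 there were 0 sperm, 0 oocyte, 1 histone and 3 ribosomal genes. DESeq2 called 1 ribosomal gene, and limma-voom and the likelihood ratio test called 0.

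The other lists did not pass in naive animals. The camera adjusted p was 0.092 for the mitochondrial unfolded protein response, 0.070 for innate immune effectors, 0.066 for germline and meiosis genes and 0.066 for neuronal markers, and these 4 passed with the block (camera adjusted p = 0.0028, 0.017, 0.0047 and 0.012). With the block and an estimated correlation they did not (adjusted p = 0.27, 0.32, 0.54 and 0.54). It was 0.72 for the endoplasmic reticulum unfolded protein response, 0.84 for antioxidant enzymes, 0.36 for the proteasome, 0.88 for the respiratory chain, 0.37 for glycolysis, 0.36 for fatty acid desaturation and oxidation, 0.28 for cuticle collagens and 0.84 for molting genes. For H3K4 methylation and for SWI/SNF and ISWI remodelling factors the camera adjusted p was 0.87 each. It was 0.56 for body wall muscle, 0.29 for intestinal and 0.53 for pharyngeal markers. Medians and means differed in sign for the endoplasmic reticulum (-0.01 and 0.04), H3K4 (-0.03 and 0.02) and SWI/SNF and ISWI lists (0.00 and -0.01), whose tests followed the means. In these lists 0 members passed in edgeR (0 in limma-voom; 1 endoplasmic reticulum and 1 fatty acid gene in DESeq2, the first also in the likelihood ratio test). At an unadjusted p below 0.05 there were 2 endoplasmic reticulum, 1 mitochondrial response, 3 fatty acid and 1 collagen genes, and 0 in the other lists. The number that rose adjusted over the list alone was 1 endoplasmic reticulum and 1 fatty acid gene. With the block 1 of each rose and 1 of each fell, and 1 collagen gene rose. Leaving out 1 library brought some of these past the threshold, whichever the direction. They were the mitochondrial response (U1, N2 or N3), immune effectors (N1 or N3), proteasome (U1), glycolysis and fatty acid genes (N2), germline (U3, U4, N1 or N2), neuronal (U1, U4, N2, N3 or B2), and muscle and pharyngeal markers (U4), with camera adjusted p from 3.3e-05 to 0.049. set-2, the H3K4 methyltransferase gene, was measured at 55.9 ± 13.7 CPM in unexposed and 56.3 ± 14.1 CPM in naive animals (0.01 ± 0.26, edgeR adjusted p = 1.00).

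In all, 27 of the 14638 genes tested rose in naive animals and 0 fell (edgeR quasi-likelihood test). With the block 161 genes changed, 144 higher and 17 lower, and 26 genes were called in both fits. Without U2, U4, N2, N3 or N4 the count without the block was 15, 16, 17, 14 or 17, and without U2, N2 or N3 the count with the block was 99, 102 or 107. With the block and an estimated correlation together, none of the 30 lists tested passed, the HIF-1 list being nearest at a camera adjusted p of 0.059.

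**Figure D1:**
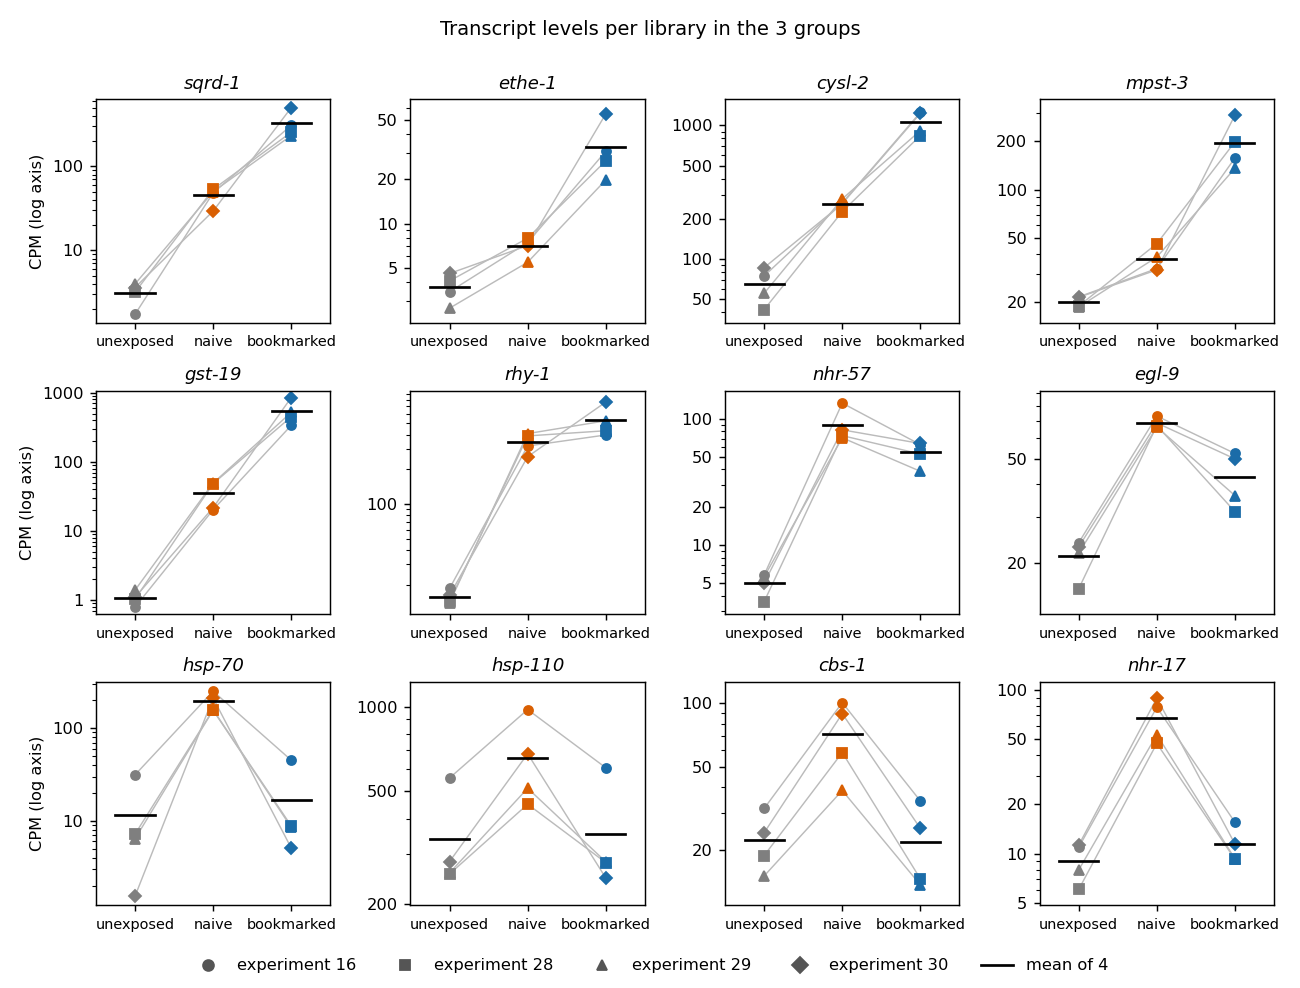
CPM (log axis, a range of its own for each gene) of 12 genes in the 12 libraries. Points are libraries, shaped by experiment and joined within it by grey lines, and black bars are the means of 4. sqrd-1 and gst-19 stepped up from unexposed to naive to bookmarked, while hsp-70, hsp-110, cbs-1 and nhr-17 had their highest means in naive animals.

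The comparison of bookmarked with unexposed animals took the early and the acute exposure together. No group had the early exposure alone, so the changes cannot be divided between the exposures. Genes of the HIF-1 and sulfur lists were among those that rose. gst-19 rose to 539 ± 221 CPM, a log2 fold change of 8.96 ± 0.51 (edgeR adjusted p = 3.8e-06). sqrd-1 rose to 325 ± 122 CPM, by 6.70 ± 0.38 (edgeR adjusted p = 3.8e-06), and rhy-1 to 529 ± 166 CPM, by 5.07 ± 0.27 (edgeR adjusted p = 3.6e-06). hif-1 was measured at 182 ± 39.5 CPM (-0.06 ± 0.20, edgeR adjusted p = 1.00).

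All 7 genes of the sulfur list that passed rose, of 22 tested, and the count was 7 adjusted over the list alone and 7 with the block (camera adjusted p = 6.3e-22, and camera adjusted p = 0.0040 with an estimated correlation). cysl-2 rose from 64.3 ± 19.7 to 1061 ± 213 CPM, by 4.04 ± 0.25 (edgeR adjusted p = 7.2e-06). mpst-3, a mercaptopyruvate sulfurtransferase, rose by 3.29 ± 0.24 to 196 ± 69.1 CPM (edgeR adjusted p = 2.9e-05). The rise was 3.15 ± 0.32 for ethe-1, to 33.0 ± 15.3 CPM (edgeR adjusted p = 5.6e-04), and 1.33 ± 0.17 for cysl-1, to 167 ± 15.6 CPM (edgeR adjusted p = 0.0029). Named after the values were seen, cysl-3 rose by 2.70 ± 0.26 (edgeR adjusted p = 2.7e-04) and cdo-1 by 2.31 ± 0.18 (edgeR adjusted p = 4.1e-05). Of 9 HIF-1 response genes 6 rose, 0 fell (0 also at an unadjusted p below 0.05 and in the other tools) and 3 did not pass. The count was 9 adjusted over the list alone and 7 with the block (median 3.44, camera adjusted p = 4.6e-64, and camera adjusted p = 3.4e-05 with an estimated correlation). R08E5.1 and R08E5.3, close copies of each other, rose by 4.54 ± 0.23 and 3.98 ± 0.22 (edgeR adjusted p = 3.6e-06 and 3.8e-06). Like them, nhr-57 rose, by 3.44 ± 0.27 to 54.6 ± 11.8 CPM (edgeR adjusted p = 4.4e-05). egl-9 rose by 1.01 ± 0.18 (edgeR adjusted p = 0.046, and 2.8e-04 with the block). This call was lost without any 1 of U1 to U4, N1 to N4, B1, B3 or B4 (edgeR adjusted p 0.059 to 0.16).

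Among 20 SKN-1 and phase II genes 4 rose and 16 did not pass. Both adjusted over the list alone and with the block 8 rose (camera adjusted p = 7.1e-33, and camera adjusted p = 0.0011 with an estimated correlation). nit-1 rose by 4.95 ± 0.31 (edgeR adjusted p = 7.2e-06), dhs-8 by 4.33 ± 0.47 (edgeR adjusted p = 8.9e-04) and wdr-23 by 0.80 ± 0.10 (edgeR adjusted p = 0.0035). gst-4 rose by 1.68 ± 0.29 (edgeR adjusted p = 0.028), a call lost without any 1 of U1 to U4, N3, N4, B2 or B4 (edgeR adjusted p 0.051 to 0.15). skn-1 was higher by 0.48 ± 0.16 (edgeR adjusted p = 1.00, and 0.018 with the block). The blocked call was lost without U1, U2, U3 or B2 (edgeR adjusted p 0.052 to 0.13). gcs-1, at 79.0 ± 16.15 CPM, and mtl-1, at 1.81 ± 0.674 CPM, did not pass (edgeR adjusted p = 1.00 each). The nspe genes nspe-3, nspe-4 and nspe-6, whose reads may not be separable, rose by 8.01 ± 1.11, 7.43 ± 0.78 and 7.67 ± 0.87 (edgeR adjusted p = 0.0057, 7.1e-04 and 0.0011). B0462.4 rose by 5.401 ± 0.50 (edgeR adjusted p = 2.4e-04). Counts assigned to the piRNA 21ur-15671 rose by 7.14 ± 0.77 (edgeR adjusted p = 8.5e-04). It lies inside sqrd-1 on the opposite strand, and an unstranded library cannot separate the 2.

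Among 58 UDP-glucuronosyltransferase genes 1 rose, also adjusted over the list alone, and 5 rose with the block (camera adjusted p = 1.5e-05), but the list's adjusted p = 0.18 with an estimated correlation. The riser was ugt-14 (4.22 ± 0.61, edgeR adjusted p = 0.0068). ugt-63 was higher by 1.72 ± 0.46 (edgeR adjusted p = 0.50, and 0.040 without B1). The 25 innate immune effectors were higher as a list (median 0.37, camera adjusted p = 3.4e-04), with an adjusted p = 0.15 with an estimated correlation. Of the immune genes 0 rose without the block (edgeR; 5 at an unadjusted p below 0.05, 1 in DESeq2, 0 in limma-voom, 1 in the likelihood ratio test). There 1 rose adjusted over the list alone and 2 with the block. dod-24 was higher by 1.16 ± 0.23 (edgeR adjusted p = 0.069, 1.9e-04 with the block, and 0.0085 to 0.044 without N1 or B3). The 15 DAF-16 targets (camera adjusted p = 0.014), 22 autophagy genes (camera adjusted p = 0.017), 16 heat shock genes (camera adjusted p = 0.023) and 19 glycolysis genes (camera adjusted p = 0.023) passed upward. These had an adjusted p = 0.18, 0.18, 0.78 and 0.78 with an estimated correlation. Of these 4 lists 0 members rose in edgeR without the block or adjusted over the list alone (1, 1, 0 and 1 at an unadjusted p below 0.05; 0 in DESeq2, limma-voom and the likelihood ratio test). With the block 1 glycolysis gene rose, ldh-1, the lactate dehydrogenase gene (0.68 ± 0.31, edgeR adjusted p = 1.00, and 0.0021 with the block). DAF-16 targets were lost without U2, U4, B1 or B3 (camera adjusted p 0.056 to 0.17), and autophagy without U2, U4 or B1 (0.070 to 0.25). Without 1 library the camera adjusted p was also above 0.05 for heat shock without U2, U3, U4 or B1 (0.14 to 0.77) and glycolysis without U2, U3, B1, B3 or B4 (0.056 to 0.28). hsp-16.2 stood at 14.3 ± 18.4 CPM in bookmarked animals (0.79 ± 0.80, edgeR adjusted p = 1.00).

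Lower as lists were 74 sperm genes (median -0.13, camera adjusted p = 0.0037), 19 vitellogenin and oocyte genes (median -0.51, camera adjusted p = 0.023), 21 germline and meiosis genes (median -0.23, camera adjusted p = 0.0051) and 12 pharyngeal markers (median -0.13, camera adjusted p = 0.045). Each had an adjusted p = 0.78 with an estimated correlation. The pharyngeal list was also lost with the block (camera adjusted p = 0.11) and with RLE size factors (camera adjusted p = 0.053). U1 held more of the sperm and oocyte transcripts than its experiment mates, at mean log2 CPM of 3.29 and 7.54 against 1.93 and 5.29 in B1. The sperm list was lost without U2, U3, B1 or B4 (camera adjusted p 0.18 to 0.70), and oocyte without U1, U2, B1 or B4 (0.26 to 0.72). The germline list was lost without U1, U2 or B4 (camera adjusted p 0.30 to 0.95) and pharynx without any 1 of U1, U4, N1, N2, or B2 to B4 (0.056 to 0.74). No member of the 4 lists fell in edgeR, also adjusted over the list alone and with the block (0 genes, and 0 at an unadjusted p below 0.05, in DESeq2, limma-voom and the likelihood ratio test). myo-2, a pharyngeal myosin, was measured at 391 ± 168 CPM in unexposed and 244 ± 146 CPM in bookmarked animals (-0.68 ± 0.42, edgeR adjusted p = 1.00).

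The remaining lists did not pass in bookmarked against unexposed animals. Of 51 cytochrome P450 genes 1 rose, also adjusted over the list alone and with the block (cyp-36A1, 2.29 ± 0.26, edgeR adjusted p = 9.4e-04, named after its values were seen), and the list's camera adjusted p was 0.22. Of 26 fatty acid genes 0 rose without the block (edgeR; 3 at an unadjusted p below 0.05, 2 in DESeq2, 0 in limma-voom, 2 in the likelihood ratio test). Adjusted over the list alone 2 rose, and 2 with the block (camera adjusted p = 0.098). The camera adjusted p was 0.38 for the endoplasmic reticulum and 0.21 for the mitochondrial unfolded protein response, 0.12 for metal-responsive genes, 0.21 for antioxidant enzymes, 0.33 for histones, 0.12 for ribosomal proteins, 0.084 for the proteasome and 0.71 for the respiratory chain. It was 0.41 for H3K4 methylation factors, 0.52 for SWI/SNF and ISWI factors, 0.14 for collagens, 0.084 for molting, 0.96 for neuronal, 0.14 for muscle and 0.96 for intestinal genes, the last with a median of 0.03 and a downward test direction. Outside the P450 genes 0 members of these lists passed in edgeR (0 in limma-voom, and 1 collagen gene in DESeq2 and the likelihood ratio test beside the fatty acid genes). At an unadjusted p below 0.05 there were 1 mitochondrial response, 1 metal-responsive, 1 histone, 1 ribosomal and 2 collagen genes. With the block 1 gene each of the mitochondrial response, metal-responsive, antioxidant and collagen lists rose and 1 molting gene fell. Without the block 0 of these passed adjusted over the list alone. Leaving out 1 library brought past the threshold the mitochondrial response (U1 or B2), P450 genes (U3 or B1), ribosomal proteins (U2, U3, or B2 to B4), proteasome (U1, U2 or B4), and respiratory chain and neuronal genes (B2). It did so for fatty acid genes (U1, B2 or B3), collagens (B3), molting (U2 or B3) and muscle (U2, U3 or B1), with camera adjusted p from 5.5e-07 to 0.048 among these lists. These lists were counted whichever their direction, which can differ between the libraries left out. set-2 was measured at 50.2 ± 17.1 CPM (-0.16 ± 0.26, edgeR adjusted p = 1.00).

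In total 54 genes rose in bookmarked against unexposed animals and 0 fell (edgeR; 35 were lower at an unadjusted p below 0.05, and 0 in DESeq2, the likelihood ratio test and limma-voom). In either direction 300 of 14638 genes had an unadjusted p below 0.05, under the share of 0.05 that chance alone gives. The 0 calls therefore do not show that no gene fell. With the block 152 genes changed, 145 higher and 7 lower, and all 54 were called in both fits. The sulfur, HIF-1 and SKN-1 lists also passed with the block and an estimated correlation together (camera adjusted p = 0.031, 0.031 and 0.032). A set of 18 genes rose in both exposed groups, where lists drawn independently of each other would share 0.0996, and 0 genes fell in both (edgeR; in bookmarked animals 35 were lower at an unadjusted p below 0.05, and 0 in the other 3 tools). With the block 61 rose in both against 1.43 for independent lists. Both comparisons use the same 4 unexposed libraries. With those libraries divided 2 and 2 between the comparisons, 2 to 8 genes rose in both without the block and 16 to 27 with it. Without the block only 2 to 10 genes were then called in naive animals, against 27 before, so fewer could be shared. With the block 45 to 196 genes were called in naive and 63 to 186 in bookmarked animals. In 20 simulations with unchanged groups the highest shared count was 0. Those groups were drawn around the values of the unexposed libraries themselves. A deviation of these libraries could therefore not produce shared calls, and the simulations cannot decide how much the shared controls add. Without U2, U3 or N3 the shared count was 11, 11 or 10.

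The comparison of bookmarked with naive animals, both freshly exposed to H2S, asked whether the early exposure altered levels after the acute one. A difference already present before the acute hour cannot be told apart from an altered response. That would need a group with the early exposure alone. sqrd-1 was higher by 2.84 ± 0.32 (325 ± 122 against 45.3 ± 10.8 CPM, edgeR adjusted p = 0.0034) and mpst-3 by 2.41 ± 0.23 (196 ± 69.1 against 37.1 ± 6.73 CPM, edgeR adjusted p = 0.0018). gst-19 was higher by 3.95 ± 0.39 (edgeR adjusted p = 0.0020). nhr-17, a nuclear receptor gene, fell by 2.56 on the log2 scale (SE 0.28), to 11.39 ± 2.97 from 67.2 ± 20.1 CPM (edgeR adjusted p = 0.0034), with 9.06 ± 2.503 CPM in unexposed animals.

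Of 22 sulfur genes 5 rose, 0 fell (edgeR; 1 at an unadjusted p below 0.05, 1 in DESeq2, 0 in limma-voom, 1 in the likelihood ratio test) and 17 did not pass. Adjusted over the list alone 7 rose and 1 fell, as with the block (7 and 1). The list passed upward (median 0.22, camera adjusted p = 1.4e-11), but not with an adjusted p = 0.070 with an estimated correlation. In fry it passed (fry adjusted p = 0.010). Beside sqrd-1 and mpst-3, cysl-2 rose by 2.04 ± 0.23 (edgeR adjusted p = 0.0036), and cysl-3, chosen after the values were seen, by 2.02 ± 0.25 (edgeR adjusted p = 0.0054). ethe-1 rose by 2.23 ± 0.31 (edgeR adjusted p = 0.014), a call lost without any 1 of N1 to N4 (edgeR adjusted p 0.051 to 0.080). cysl-1 was higher by 1.00 ± 0.17 (edgeR adjusted p = 0.053, 3.0e-04 with the block and 0.045 without U2). cbs-1, the cystathionine beta-synthase gene, went the other way, at 71.7 ± 28.5 CPM in naive and 21.99 ± 9.77 CPM in bookmarked animals against 22.4 ± 7.16 CPM in unexposed ones (-1.70 ± 0.38, edgeR adjusted p = 0.29). It fell with the block (-1.71 ± 0.11, edgeR adjusted p = 1.4e-06).

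The 9 HIF-1 response genes divided. R08E5.1 and R08E5.3 rose by 2.59 ± 0.21 and 2.51 ± 0.21 (edgeR adjusted p = 5.6e-04 each) and made up, with cysl-2, the 3 that rose. Of the list 0 fell without the block (edgeR, 0 in DESeq2, limma-voom and the likelihood ratio test; 2 at an unadjusted p below 0.05). Adjusted over the list alone 4 rose and 2 fell, and with the block 3 rose and 2 fell. The 2 lower with the block were egl-9 (-0.70 ± 0.18, edgeR adjusted p = 0.57, and 0.0044 with the block) and nhr-57 (-0.73 ± 0.24, edgeR adjusted p = 1.00, and 0.031 with the block). The blocked call of nhr-57 was lost without any 1 of U4, N1 to N4 or B1 to B3 (edgeR adjusted p 0.056 to 0.14). The call of egl-9 was lost when replicate 2 was left out of every group (edgeR adjusted p = 0.058). rhy-1 was higher by 0.63 ± 0.22 (edgeR adjusted p = 1.00, and 0.38 with the block), and hif-1 differed by -0.28 ± 0.20 (edgeR adjusted p = 1.00). As a list the HIF-1 genes passed upward (median 0.63, camera adjusted p = 2.3e-07), with an adjusted p = 0.070 with an estimated correlation. In fry they passed (fry adjusted p = 0.0035).

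Of 20 SKN-1 and phase II genes 1 rose, nit-1 (2.22 ± 0.27, edgeR adjusted p = 0.0054), while 3 rose adjusted over the list alone and 3 with the block. The list passed (camera adjusted p = 1.7e-08), with an adjusted p = 0.073 with an estimated correlation. In fry it did not pass (fry adjusted p = 0.059). gst-30 was higher by 2.196 ± 0.66 (edgeR adjusted p = 0.90, and 0.0025 with the block). gst-4 was higher by 1.31 ± 0.28 (edgeR adjusted p = 0.23, and 0.017 with the block, lost without N4, B1 or B2 at 0.055 to 0.094). skn-1 and gcs-1 differed by -0.08 ± 0.16 and 0.02 ± 0.21 (edgeR adjusted p = 1.00 each), as did mtl-1 and set-2, by -0.06 ± 0.42 and -0.17 ± 0.26 (edgeR adjusted p = 1.00 each). R08F11.4 rose by 4.12 ± 0.52 (edgeR adjusted p = 0.0057) from 1.61 ± 0.832 CPM in naive animals, close to the 0.973 ± 0.194 CPM of unexposed ones. B0462.4 rose by 3.04 ± 0.43 (edgeR adjusted p = 0.016), a call lost without any 1 of N1 to N4 or B2 to B4 (edgeR adjusted p 0.051 to 0.080).

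Some heat shock genes were lower in bookmarked than naive animals with the block. hsp-70 stood at 16.9 ± 18.9 CPM against 194 ± 45.6 CPM in naive animals (-3.52 ± 0.89, edgeR adjusted p = 0.50). It fell with the block (-4.07 ± 0.58, edgeR adjusted p = 0.033). That blocked call was lost without any 1 of U1 to U3, N2, N3 or B1 to B4 (edgeR adjusted p 0.055 to 0.17). hsp-16.2 and hsp-16.41 differed by -2.64 ± 0.82 and -2.81 ± 1.12 (edgeR adjusted p = 1.00 each, and 0.060 and 0.097 with the block). hsp-110, chosen after the values were seen, differed by -0.89 ± 0.37 (edgeR adjusted p = 1.00) and fell with the block (edgeR adjusted p = 0.0010). Of the 16 heat shock genes 0 fell without the block (edgeR; 5 at an unadjusted p below 0.05, 1 each in DESeq2, limma-voom and the likelihood ratio test). The count was 1 adjusted over the list alone and 3 with the block. The list passed downward (median -0.17, mean -0.71, camera adjusted p = 4.1e-06), but its adjusted p = 0.36 with an estimated correlation did not pass. B1 was above B2 to B4, with hsp-70 at 45.2 CPM against at most 8.83 CPM.

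Beside nhr-17, 3 genes fell without the block. aip-1, an arsenite-inducible gene that acts with the proteasome, fell by 1.21 on the log2 scale (SE 0.20, edgeR adjusted p = 0.044), lost without any 1 of U1 to U3, N1 to N4 or B2 to B4 (edgeR adjusted p 0.066 to 0.17). lact-4 fell by 1.16 (SE 0.18, edgeR adjusted p = 0.034), lost without any 1 of U1 to U4, N1 to N4, B2 or B3 (edgeR adjusted p 0.052 to 0.14). The nuclear receptor gene nhr-3 fell by 1.09 (SE 0.17, edgeR adjusted p = 0.032), lost without any 1 of U1 to U4, N1 to N4, B3 or B4 (edgeR adjusted p 0.050 to 0.15). With the block these 3 passed at an edgeR adjusted p of 2.2e-04, 0.0032 and 3.6e-04. In the authors' comparison table aip-1, lact-4 and nhr-3 were higher in naive than unexposed animals, by 1.69, 1.97 and 1.21. In bookmarked against unexposed animals they differed by 0.48, 0.81 and 0.11. scp-1, a homolog of the sterol sensor SCAP, was at 110 ± 26.6 CPM in naive and 47.05 ± 15.9 CPM in bookmarked animals (-1.23 ± 0.24, edgeR adjusted p = 0.13, 1.0e-04 with the block and 0.021 without B1). cnp-3 differed by -1.65 ± 0.30 (edgeR adjusted p = 0.081, and 4.8e-05 with the block), F45E1.4 by -1.19 ± 0.30 (edgeR adjusted p = 0.50, and 0.0022 with the block) and R11A5.3 by -3.32 ± 0.65 (edgeR adjusted p = 0.13, and 0.0025 with the block). In the authors' table scp-1, cnp-3, F45E1.4 and R11A5.3 differed by 1.37, 2.15, 1.04 and 4.04 in naive against unexposed animals. In bookmarked against unexposed animals the values were 0.15, 0.49, -0.16 and 0.72. The 21ur-15671 counts inside sqrd-1 differed by 2.91 ± 0.59 (edgeR adjusted p = 0.15, 1.0e-04 with the block and 0.027 without U3).

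Among the other lists, 27 histone genes were higher (median 0.16, camera adjusted p = 6.4e-04), lost without N1 or B3 (camera adjusted p 0.059 to 0.23) and at an adjusted p = 0.36 with an estimated correlation. The 12 pharyngeal markers were lower (median -0.27, camera adjusted p = 0.0098), lost without N1, N4 or B2 (camera adjusted p 0.081 to 0.15) and at an adjusted p = 0.63 with an estimated correlation. Neither list had a member past the threshold in edgeR, adjusted over the list alone or with the block (0 genes, 2 histone and 0 pharyngeal genes at an unadjusted p below 0.05, 0 in DESeq2, limma-voom and the likelihood ratio test). Molting genes missed the threshold (camera adjusted p = 0.064) and passed downward with the block (camera adjusted p = 0.0038), but not with an estimated correlation (adjusted p = 0.82, and 0.68 with the block). The camera adjusted p was 0.81 for the endoplasmic reticulum and 0.71 for the mitochondrial unfolded protein response, 0.16 for metal-responsive genes, 0.46 for antioxidant enzymes, 0.17 for DAF-16 targets, 0.10 for immune effectors, 0.36 for P450 and 0.92 for UDP-glucuronosyltransferase genes. It was 0.67 for H3K4 methylation factors, 0.70 for SWI/SNF and ISWI factors, 0.56 for ribosomal proteins, 0.56 for the proteasome, 0.81 for the respiratory chain, 0.28 for glycolysis, 0.50 for fatty acid genes and 0.10 for autophagy. For stage and tissue lists it was 0.81 for collagens (median 0.10, test downward), 0.70 for sperm, 0.34 for oocyte (median -0.03, test upward), 0.43 for germline, 0.10 for neuronal, 0.064 for muscle and 0.32 for intestinal genes. The respiratory chain list had a median of -0.01 and a mean of 0.00 with an upward test, and the P450 list a median of 0.00 and a mean of -0.02. In these lists 0 members passed in edgeR, also adjusted over the list alone, in DESeq2, limma-voom and the likelihood ratio test. At an unadjusted p below 0.05 there were 7 UDP-glucuronosyltransferase genes, 2 each of the endoplasmic reticulum, immune, P450 and fatty acid lists, and 1 each of autophagy and collagens. With the block 2 UDP-glucuronosyltransferase genes rose and 1 fell, and 1 endoplasmic reticulum gene rose and 1 fell. With the block 1 gene each of the immune, glycolysis, fatty acid and collagen lists rose, and 2 P450 and 1 autophagy gene fell. Leaving out 1 library brought past the threshold metal-responsive genes (N3 or B4), immune effectors (N2, B1 or B3), ribosomal proteins (N4, B2 or B4), and respiratory chain and fatty acid genes (B2). It did so for glycolysis (N1 or B2), autophagy (B1), collagens (B3), molting (N2 or B3) and sperm (N1 to N3, B1, B2 or B4) genes. It also did so for oocyte (N2, B1 or B4), germline (N4 or B2), neuronal (N2, N3, B1 or B4), muscle (U3, N2, N3, B1 or B3) and intestinal genes (N2), with camera adjusted p from 1.1e-06 to 0.049 among all these lists. All were counted whichever their direction, which can differ between the libraries left out.

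In all, 23 genes differed between bookmarked and naive animals, 19 higher and 4 lower (edgeR). With the block 155 differed, 82 higher and 73 lower, and all 23 were called in both fits. Under the block the share of higher genes was 52.9%, against 52.7% in limma-voom, 47.8% in edgeR with RLE size factors and 43.6% in DESeq2, so which direction held more genes changed between these settings. Without N1, N2 or N4 the count without the block was 13, 15 or 13, and without N2, N4 or B2 the count with the block was 91, 81 or 88. With the block and an estimated correlation together none of the 30 lists passed. To compare response sizes on separate libraries, genes were called in naive against unexposed animals from 2 experiments and measured in the other 2. Of 6 such divisions 1 gave enough genes, 18, with a slope of bookmarked on naive log2 changes of 1.13. With the block all 6 gave slopes, from 0.76 to 1.17 over 20 to 86 genes. Both changes were taken against the same unexposed libraries, whose error enters both and can draw the slope towards 1.

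**Figure D2:**
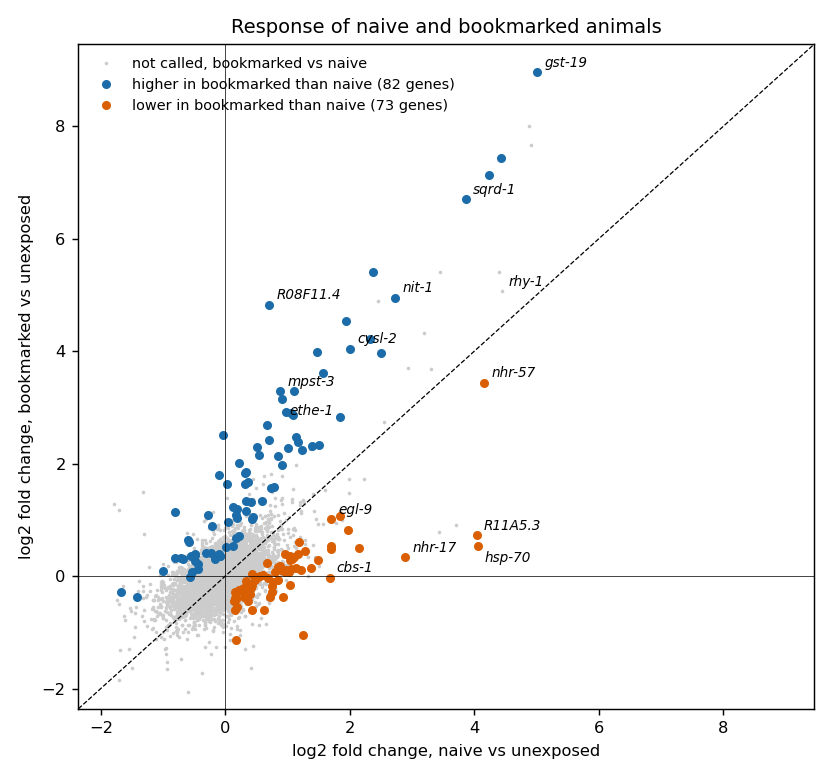
Log2 fold change of bookmarked against unexposed (vertical axis) and naive against unexposed animals (horizontal axis), without the block, for the 14638 genes tested. Coloured points are the 82 genes higher and 73 lower in bookmarked than naive animals with the replicate block, and the dashed line marks equal change. sqrd-1, gst-19 and cysl-2 lie above the line, and hsp-70, nhr-17 and cbs-1 below it near 0 on the vertical axis.

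**Figure D3:**
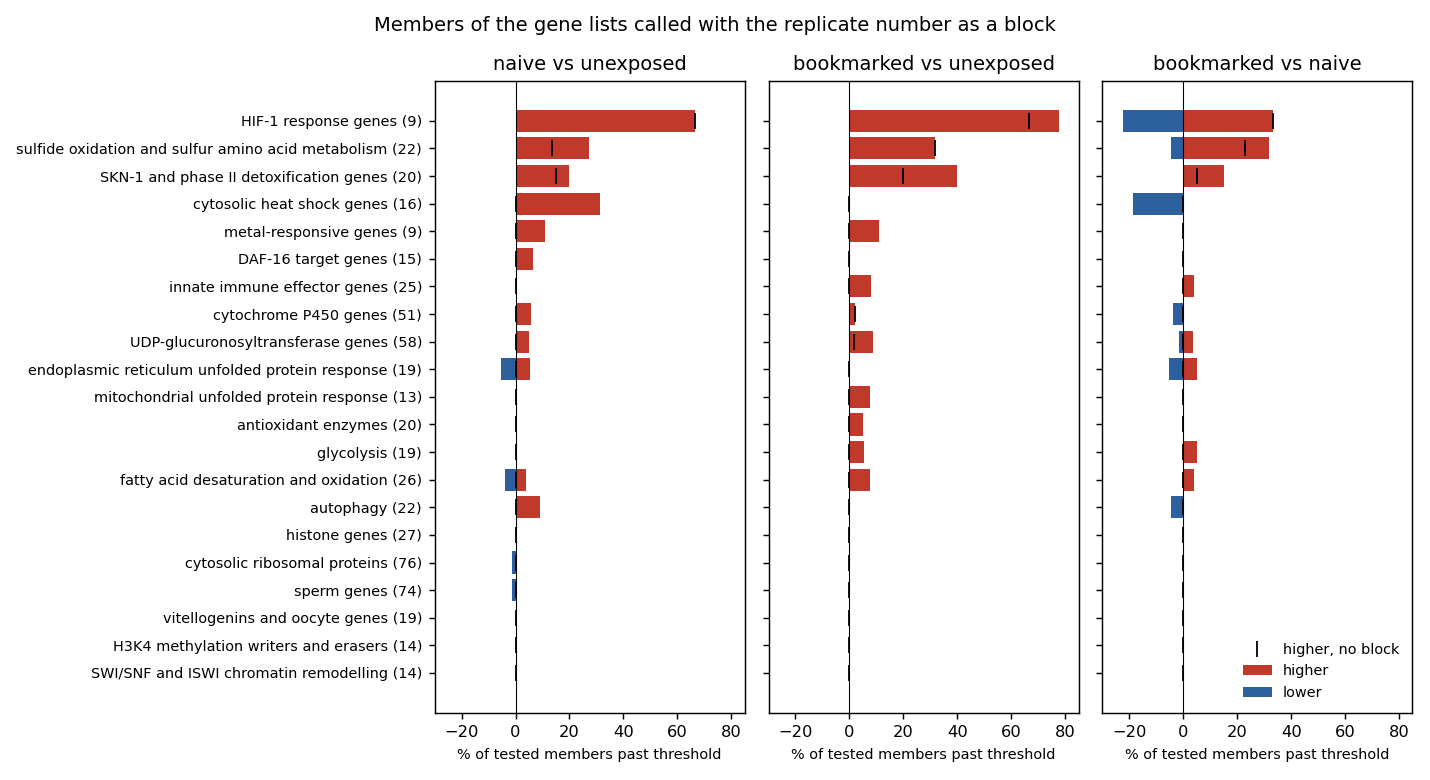
Percentage of the tested members (number in parentheses) of 21 gene lists that were called higher (red, to the right) or lower (blue, to the left) with the replicate block in each comparison. Black ticks mark the percentage called higher without the block. With the block, 3 of 9 HIF-1, 7 of 22 sulfur and 3 of 20 SKN-1 genes were higher in bookmarked than naive animals, and 2 HIF-1 and 1 sulfur gene lower. Of 16 heat shock genes, 5 were higher in naive than unexposed and 3 lower in bookmarked than naive animals.

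Libraries differed between experiments in transcripts that depend on developmental timing. The first principal component held 69.2% of the variance and set experiments 16 and 30 apart from 28 and 29 in every group. The 74 sperm genes had a mean log2 CPM of 2.29, 5.63, 4.71 and 2.03 in experiments 16, 28, 29 and 30, a 12.1-fold range. The 19 vitellogenin and oocyte genes spanned a 10.9-fold range and the 141 cuticle collagens a 2.57-fold range. Sperm genes were higher in experiments 28 and 29 than in 16 and 30 in all 3 groups. The order of the experiments differed between groups for the oocyte and collagen lists, with U1 above U3 for oocyte genes (7.54 against 6.87) but N1 below N3 and B1 below B3. U1 stood above N1 and B1 of its experiment for the sperm list (3.29 against 1.67 and 1.93). The replicate block removes differences shared by the 3 groups, lowering the common biological coefficient of variation from 0.452 to 0.148.

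**Figure D4:**
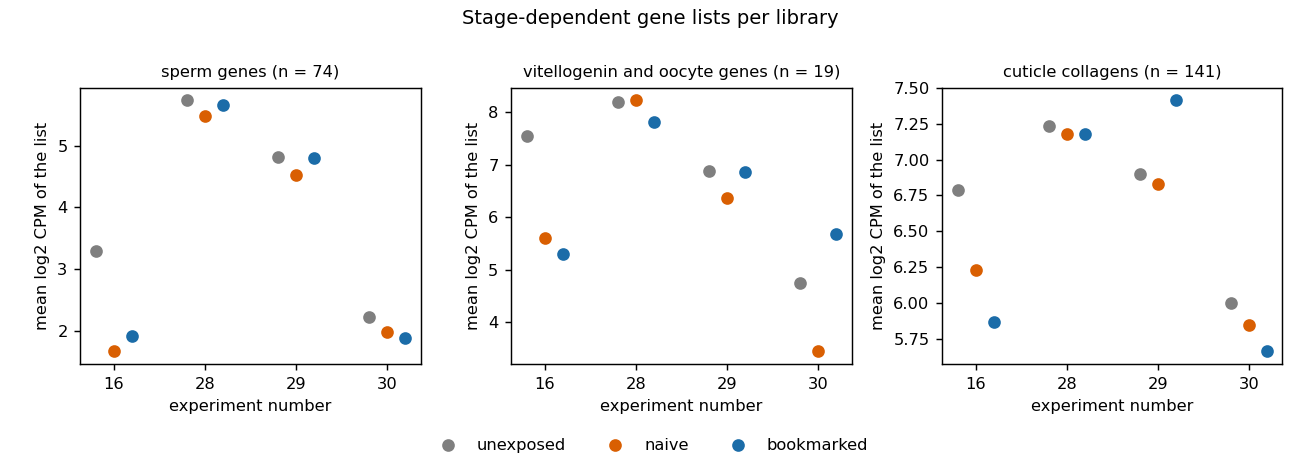
Mean log2 CPM of sperm, vitellogenin and oocyte, and cuticle collagen genes in each of the 12 libraries, by experiment number and coloured by group. Sperm genes stand at 5.63 and 4.71 on average in experiments 28 and 29, against 2.29 and 2.03 in experiments 16 and 30.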

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

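The tests of a shift on the leading component behind the opposite directions and of naive RNA in the unexposed replicate 1 library were chosen only after their results were seen.

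In each group of 4 libraries, the highest and lowest library were compared with the rest by Dixon's ratio, the gap to the nearest library over the whole range. For genes the ratio was taken on log2 CPM (prior count 2), while the levels printed are CPM. For total counts it was taken on the counts. Chance alone makes a library stand out in about 1 of 20 groups. Of 318 groups tested, over 105 genes and the total counts, 21 stood out against 15.9 by chance. Unexposed replicate 1 had the highest gcs-1 (90.9 CPM against 61.9 to 62.4, ratio 0.977), hsp-110 (558 against 255 to 282, ratio 0.871) and hsp-16.41 (24.4 against 1.75 to 2.66, ratio 0.848), the lowest R08E5.1 (1.81 against 2.04 to 2.08, ratio 0.840) and the highest total (13818462 counts against 9268745 to 9870127, ratio 0.868). At these low R08E5.1 levels counting error is large beside the gap. Bookmarked replicate 1 had the highest dnj-13 (378 CPM against 166 to 185, ratio 0.873), hsp-110 (606 against 246 to 281, ratio 0.853), hsp-16.41 (49.8 against 2.19 to 3.65, ratio 0.842) and scp-1 (70.9 against 38.3 to 40.4, ratio 0.913). Naive replicate 1 had the highest fbf-1 (29.6 against 19.7 to 20.6 CPM, ratio 0.891) and the highest total (14640115 counts against 9252823 to 10033921, ratio 0.855).

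The other 10 cases were single genes. Unexposed replicate 3 was highest for lact-4 (26.4 against 21.03 to 21.4 CPM, ratio 0.919) and rpl-29 (1273 against 941 to 986 CPM, ratio 0.847). Naive replicate 3 was lowest for nhr-3 (39.9 against 43.1 to 43.2 CPM, ratio 0.968), naive replicate 4 for sqrd-1 (29.4 against 48.4 to 53.4 CPM, ratio 0.836) and naive replicate 2 for T28F4.1 (11.7 against 14.96 to 15.7 CPM, ratio 0.840). Bookmarked replicate 4 was lowest for aagr-1 (30.2 against 36.4 to 37.4 CPM, ratio 0.868) and rec-8 (15.5 against 29.6 to 33.7 CPM, ratio 0.834). Bookmarked replicate 3 was lowest for dod-24 (83.4 against 122 to 130 CPM, ratio 0.859). Bookmarked replicate 2 was highest for atg-18 (65.2 against 46.4 to 49.1 CPM, ratio 0.830) and lowest for tpi-1 (246 against 321 to 336 CPM, ratio 0.856).

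Libraries of experiments 16 and 30 stood apart from those of 28 and 29 on the leading component, which held 69.2% of the variance. With every library thinned to the lowest total the component still held 68.5%, which argues against sequencing depth. All 4 stage lists tested (sperm, oocyte, collagen and molting) had larger loadings on it than 95% of random lists of like expression. The sulfur list, which is no stage list, passed the same bound (95.3% of random lists, beside 97.0% for molting), so the bound is not specific to stage. A difference in timing within the larval stage is a candidate explanation for the sperm, oocyte and collagen lists, each above all 10000 random lists. Whether the timing differed, and why, was not tested directly.

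Genes lower in bookmarked than in naive animals stood beside genes that were higher, 73 and 82 with the block. A shift along the leading component would move each gene by its slope on it, and the shift between the groups gave a median of 0.0212% of the log2 difference (quartiles -1.24% to 1.52%), so a stage difference along that component does not account for them. A stage difference of another kind was not tested and stays open; the molting list was lower in bookmarked than naive animals with the block (camera adjusted p = 0.0038, and 0.68 with an estimated correlation). With all counts thinned to the lowest total, 96.1% of the 155 genes were called in the same direction, which argues against depth. The early exposure stays among the open explanations, as do differences in handling between the groups, which were not tested.

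Several heat shock transcripts were high in replicate 1 of the unexposed and bookmarked groups, both from experiment 16. If naive RNA had entered the unexposed library, its heat shock genes would need a share of 10.7% to 18.01%. The 19 other genes called higher in naive than unexposed animals needed a median of 0.988% (upper quartile 5.15%). This argues against it for those genes. They were called with this library among the controls, a choice that favours low shares and limits the test. In the bookmarked library the heat shock genes need 15.5% to 38.9%. The other genes there were a separately chosen set, 19 genes lower in bookmarked than naive animals. They needed a median of 11.36% (quartiles -19.4% to 26.8%). That median was past the bound of 5% written before, but the quartiles span 0, so naive RNA there cannot be told apart from a response of those animals. The requirement on the quartiles was added after the value was seen. A heat or handling stress in experiment 16 was not tested.

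Chance was examined with other splits of the 8 libraries of each comparison, the third group kept. Without the block 2 of 35 splits, the real one included, gave as many genes in each comparison, so chance is not excluded. The other split parted experiments 16 and 30 from 28 and 29 and called 3063, 2740 and 3684 genes against the real 27, 54 and 23, which points to the structure of the samples by experiment. Among splits that part all pairs, as the real one does, the highest other count was 0. With the block there are 8 splits, too few for a share below 0.05; the real split alone (1 of 8) gave 161, 152 and 155 genes, and the highest other count was 0, 2 and 0.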

How the results depend on the processing

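The alternatives to the fit with the block, the block with an estimated correlation, the slope with the block and the genes added by name were chosen only after the results were seen. For named genes in their comparisons, 3776 comparisons with another setting were made without the block; 3506 kept their side of the threshold, 142 lost a call, 128 gained one and 0 reversed. For genes called with the block only, 930 of 1113 kept it, 183 lost it and 0 reversed. For lists, 1313 of 1530 stayed, 133 were lost, 84 gained and 0 reversed. Only a gene or list that passed in both settings could count as reversed. A gained call could thus have the opposite direction to the main fit, and 0 reversed does not cover it. Scaling shifted the median of all genes by less than 0.1 on the log2 scale. Where counts moved by more than 1.5 times, the cause was not tested, except that stricter thresholds call fewer genes by construction.

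Counts of genes in naive against unexposed animals were 27 as reported, 80 in DESeq2, 56 in the likelihood ratio test, 161 with the block, 13 at an adjusted p below 0.01 and 14 to 28 without 1 library. Bookmarked against unexposed animals gave 54, with 84 in DESeq2, 152 with the block and 43 to 54 without 1 library. Bookmarked against naive animals gave 23, with 62 in DESeq2, 50 in the likelihood ratio test, 155 with the block, 13 at an adjusted p below 0.01 and 13 to 23 without 1 library. With the block, DESeq2 called 261 and 282 genes in the first and last comparison. An adjusted p below 0.01 left 96, 100 and 76, and an absolute log2 fold change of at least 1 left 74, 90 and 68. Without 1 library the blocked counts were 99 to 181 in the first and 81 to 174 in the last comparison, and in the second none moved by more than 1.5 times, the highest being 201. Without replicate 1 in every group the first was 103; without replicate 2 the 3 counts were 51, 78 and 64; without replicate 4 the last 2 were 100 and 95.

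Calls shared by the exposed groups were 18, with 11 under upper-quartile factors, 38 in DESeq2, 29 in the likelihood ratio test, 10 with only the 8 libraries compared, 61 with the block, 9 at an adjusted p below 0.01 and 10 to 16 without 1 library. Of the 30 lists, 13, 13 and 6 passed in the 3 comparisons; 6, 3 and 0 did with an estimated correlation, 3, 3 and 2 in fry, and 0, 3 and 0 with the block and an estimated correlation. Those that passed in fry were the HIF-1 and sulfur lists in each comparison, and the SKN-1 list in the first 2. Without 1 library 10 to 17, 9 to 17 and 6 to 13 lists passed. In simulated counts with no differences shared within an experiment, 15.3% of changes of 1 on the log2 scale were recovered without the block.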

Other observations

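The genes here were chosen only after their values were seen.

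C31C9.2, a phosphoglycerate dehydrogenase homolog, rose from 214 ± 28.6 CPM in unexposed to 1141 ± 184 CPM in bookmarked animals, by 2.41 ± 0.20 on the log2 scale (edgeR adjusted p = 6.7e-05), and by 1.72 ± 0.19 against naive animals (edgeR adjusted p = 0.0034). F26H9.5, a phosphoserine aminotransferase homolog, rose by 2.14 ± 0.24 against unexposed animals (edgeR adjusted p = 8.9e-04) and was higher by 1.30 ± 0.23 than in naive ones (edgeR adjusted p = 0.067, 0.0013 with the block and 0.049 without naive replicate 3). Y62E10A.13, a phosphoserine phosphatase homolog, rose by 1.63 ± 0.29 against unexposed animals (edgeR adjusted p = 0.036, and 1.1e-05 with the block) and was higher by 1.32 ± 0.28 than in naive ones (edgeR adjusted p = 0.23, and 1.3e-04 with the block). The call against unexposed animals was lost without any 1 of unexposed replicates 1, 2 or 4, naive replicates 2 or 4, or bookmarked replicates 2 to 4 (edgeR adjusted p 0.057 to 0.16). No list holding these 3 genes had been fixed, so they were not tested as a group. Y37A1B.5, a selenium-binding protein homolog, rose from 90.2 to 675 ± 203 CPM in bookmarked animals, by 2.90 ± 0.27 (edgeR adjusted p = 2.7e-04).

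In the table deposited by the authors 43, 75 and 39 genes had an adjusted p below 0.05 in the 3 comparisons, of which 43, 75 and 30 were higher and 0, 0 and 9 lower. Of these, 26, 50 and 21 were also called without the block and 37, 65 and 35 with it.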
